A study of Mus musculus with 6 samples.

How the data were processed

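RNA from 3 samples of B cells selected from the spleens of wild-type mice and 3 spleens of passage-1 recipients of adoptively transferred cells of the Eµ-SOX11CCND1 model was sequenced by the authors. Per the labels, 50 ng of total RNA (RNeasy mini kit) went into libraries with the NEBNext Ultra Directional kit. The values are raw counts per gene, deposited as 1 table for all 6 samples. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with HISAT2 to GRCm39 and counted with featureCounts; versions, options and the counting strand are not stated. The labels name mice, but whether each library is an independent donor is not stated, so p-values measure the spread between these samples. The 3 P1 libraries shared their most counted Ighv and Igkv genes, so they may hold 1 transferred clone. P-values may therefore not cover the spread between tumours of the model. The 3 WT columns could not be tied to particular mice and are called WT A, B and C in column order. P1 replicates are numbered 3, 4 and 5, as labelled.

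The table had 56884 genes, of which 51948 (91.3%) were given a symbol by gene ID. Coordinates are those of the table. Library totals were 13978445, 14266132 and 12196413 counts in WT A, B and C and 10363396, 7510327 and 7969649 in P1 replicates 3, 4 and 5, with TMM factors of 1.184, 1.094, 1.088, 1.13, 0.578 and 1.086. Chi-square per degree of freedom was 22.2 to 23.5 between WT libraries and 139.7 to 290.5 between P1 libraries, so no 2 libraries were repeats of the same counts. The first principal component held 72.9% of the variance and the second 12.5%. The Y chromosome genes checked, Ddx3y, Eif2s3y, Kdm5d and Uty, had at most 1 count in any library.

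Genes were filtered with filterByExpr by group, normalised with TMM and tested with the edgeR (4.0.16, R 4.3.3) quasi-likelihood F-test with robust dispersion, without covariates, since the labels give no batch, sex or pairing. P-values were adjusted by Benjamini-Hochberg at 0.05, and this test gives the adjusted p-values of single genes throughout the text. At an unadjusted p under 0.05, 3457 genes were higher and 2733 lower. Normalised CPM are scaled to the TMM-adjusted library totals, and ± is the SD over 3 libraries for CPM and shares and the standard error for log2 fold changes. A single gene named as risen or fallen had all 3 P1 libraries on the same side of all 3 WT libraries. Genes with 0 counts in a group were given a lower bound against 3 counts over that group, and genes with 1 to 3 counts a ratio with an exact 95% counting interval.

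Gene lists, groups, tests, the alternatives and the rule for naming genes were set before the data were examined. Of 860 entries in 36 lists, 856 matched a gene, 7 of them through a synonym, and Phb1, Rigi, Atp5pb and Ahsp did not. The 34 lists with at least 5 tested members were tested with limma (3.58.1) camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry tests a list against no change, so a fry result is not a call against other genes. With the preset correlation 23 lists passed, 14 up and 9 down, against 0 with an estimated correlation. The driver gene list (2 tested) and the sex-linked list (1 tested, Xist, not past the threshold) were too small for this test. Estimated correlations ran from -0.037 to 0.797, so the preset of 0.01 understates the correlation of many lists and a call from it is weak evidence. The version with an estimated correlation has few degrees of freedom with 3 libraries per group, so its lack of calls decides little. The counts of members come from the same libraries and correlated genes, and 27.9% of all tested genes were called.

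The genes named are Sox11 and Ccnd1, then the 10 largest positive and the 10 largest negative log2 fold changes. Those 20 had to have an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap of the groups, leaving out antigen receptor segments, models without a curated symbol, pseudogenes and mitochondrial or ribosomal RNA genes. From each list the 3 members with the smallest adjusted p and the 1 with the highest mean CPM were eligible, and any member of a list of 26 or fewer. The most counted Ighv, Igkv and Iglv gene of each library was named, with 95% binomial intervals for its share, which treat reads as independent and cover counting error alone. The group difference of that share was tested by exact permutation of the 6 libraries.

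The gene test was tested on simulated data for the comparison of P1 spleen with WT B cells, run on 15462 genes with the dispersions of these libraries. With 200 genes changed, a first run recovered 0 of 100 genes changed 2-fold and 16 of 100 changed 4-fold, with 1 of 15262 unchanged genes among 17 calls (5.9%). A second run, with a 16-fold step added after the first was seen, recovered 6 of 67 (9%) at 2-fold, 30 of 67 (44.8%) at 4-fold and 63 of 66 (95.5%) at 16-fold. Its 110 calls included 11 unchanged genes (10%), above the nominal rate. Median estimated log2 changes were 1.05 and 1.94 in the first run and 1.06, 1.95 and 3.97 in the second. A list of 40 genes moved 2-fold passed camera (adjusted p = 2.56e-21), and 0 of 34 unmoved lists did, in simulated genes that vary independently.

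Alternatives were DESeq2 (1.42.0) size factors, TMM without immunoglobulin, haemoglobin, mitochondrial and ribosomal RNA genes, B-cell-centred scaling, no filter, at least 10 CPM in 3 libraries, the DESeq2 Wald test, limma voom, a fold threshold of 2 (glmTreat) and leaving out each library. Library totals without TMM factors were added after the data were seen. B-cell-centred scaling makes the mean log2 level of the pan-B cell genes equal in all libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.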

Results

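Spleens of passage-1 (P1) recipients of the Eµ-SOX11CCND1 mantle cell lymphoma model held high levels of both driver genes and of genes of dividing cells. A single pair of immunoglobulin V genes, Ighv1-69 and Igkv12-44, took most of the V-gene counts in each of the 3 recipients. Genes of mature follicular B cells, above all Cr2 and Fcer2a, were far lower than in the selected B cells of wild-type (WT) spleens. Markers of red cell precursors, neutrophils and T cells were much higher in the recipient spleens than in the selected WT B cells. The B cell selection of the WT samples alone could give this.

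Of 15462 tested genes, 2618 were higher and 1702 lower in P1 spleen than in WT B cells (edgeR quasi-likelihood test, n = 3 per group, Benjamini-Hochberg), 27.9% of those tested. At least 4-fold changes were estimated for 1857 of the higher and 774 of the lower genes, and 60.6% of all calls were higher. In 4277 of the 4320 called genes the libraries of the 2 groups did not overlap, and the groups were apart in 47.8% of tested genes against the 10% that chance gives. The numbers of higher and lower genes were 1715 and 827 without WT A, 1644 and 815 without WT B, and 1991 and 979 without WT C. They were 2818 and 1638 without P1 replicate 4, the library with the largest mitochondrial share. Scaling the libraries to equal levels of pan-B cell genes moved the median log2 fold change of all genes from 0.02 to 2.87 and gave 13872 higher and 112 lower genes, 99.2% higher. A gene between 0 and 2.87 under that scaling lay above 0 but below the median of all genes. Counts of list members called under that scaling hold this shift too. Camera compares a list with the other genes, which are shifted as well, so a list's place among them changes little. A list that still passed camera under that scaling is therefore not shown to be lower for a reason other than B cell content. The 2 groups differ in cell selection, genotype and tumour at once, and these could not be separated.

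Both driver genes rose. Sox11 (chromosome 12, 27384263 to 27392573) had 0, 1 and 0 counts in the WT libraries and 956, 4066 and 5584 in P1 replicates 3, 4 and 5. Its log2 fold change was 14.05 ± 1.38 (standard error, edgeR adjusted p = 0.000604), a ratio of 19556 with a counting interval of 3509 to 772483. Ccnd1 (chromosome 7, 144483668 to 144493662) rose by 5.28 ± 0.88 (adjusted p = 0.00342), from 11.2 ± 9.69 normalised CPM (mean ± SD) to 435 ± 296. P1 replicate 3 was the lowest of the 3 recipients for both, with 82.2 CPM of Sox11 against 941 and 648, and 105 CPM of Ccnd1 against 522 and 677. Whether the transgenes are of mouse or human sequence is not stated, and these counts hold only the reads that mapped to the mouse genes, which human transcripts would do in part. In the list of driver genes, 2 of 2 tested members were higher, and also when adjusted over the list alone.

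**Figure D1:**
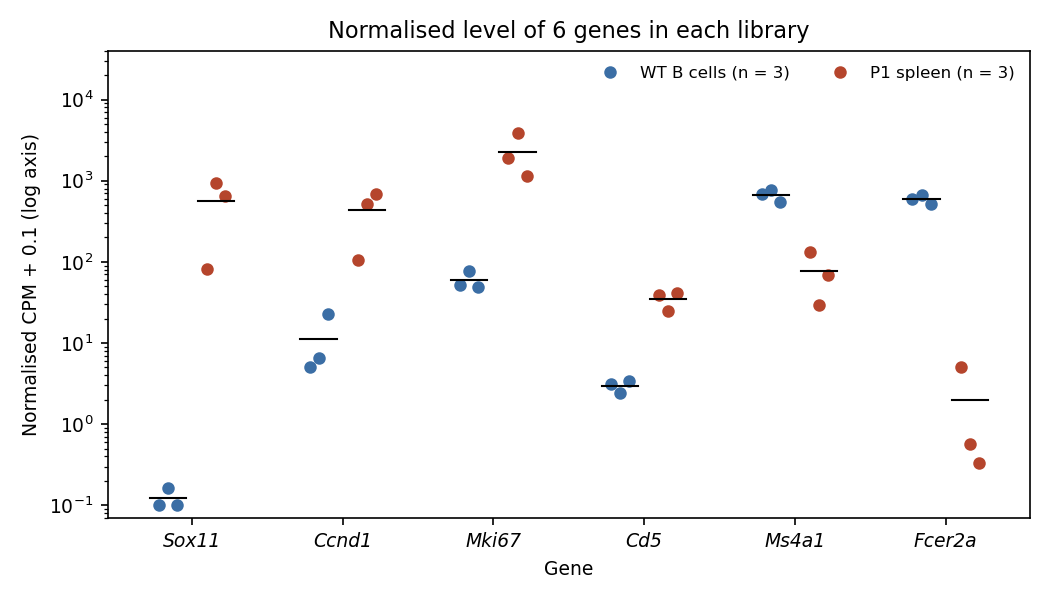
Normalised CPM of 6 genes in each library, with group means as bars. Log2 fold changes were 14.05 for Sox11, 5.28 for Ccnd1, 5.25 for Mki67 and 3.59 for Cd5, against -3.13 for Ms4a1 and -8.13 for Fcer2a, which became -0.42 and -5.41 under B-cell-centred scaling.

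The P1 spleens shared the same most counted V genes, while the WT libraries each held many. Ighv1-69 (chromosome 12, 115586781 to 115587215) took 55.53% (95% interval 53.89 to 57.17), 92.59% (90.14 to 94.47) and 96.8% (96.03 to 97.43) of Ighv counts in P1 replicates 3, 4 and 5. Igkv12-44 (chromosome 6, 69791615 to 69792138) took 62.96% (61.38 to 64.5), 97.64% (96.34 to 98.48) and 97.23% (96.4 to 97.87) of Igkv counts. In the WT libraries the most counted genes were Ighv1-9 (6.309%), Ighv1-80 (6.195%) and Ighv3-6 (9.338%), and Igkv5-39 (7.868% and 5.424%) and Igkv3-4 (7.972%). The mean top share was 7.28 ± 1.78% in WT and 81.6 ± 22.7% in P1 for Ighv (exact permutation p = 0.1, n = 3 per group, the smallest this design can give). It was 7.09 ± 1.44% and 85.9 ± 19.9% for Igkv (exact permutation p = 0.1, n = 3 per group). The effective number of genes went from 36.6 ± 7.29 to 1.81 ± 1.20 for Ighv and from 37.8 ± 7.87 to 1.53 ± 0.83 for Igkv. Iglv1 was the most counted Iglv gene in the WT libraries (692 of 810, 920 of 1182 and 827 of 909 counts) and in P1 replicate 3 (151 of 189), while the top genes of replicates 4 and 5, Iglv2 and Iglv1, had 4 and 2 counts. Reads of related V genes can be assigned to the wrong gene, so these names are uncertain between close paralogs.

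**Figure D2:**
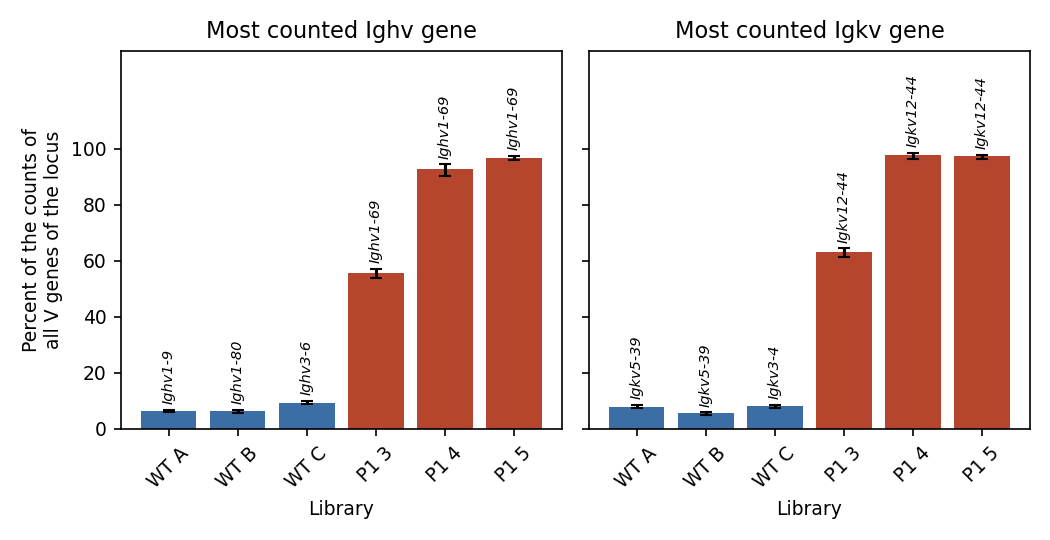
Share of the most counted Ighv and Igkv gene in each library, with 95% intervals that cover counting error alone. Ighv1-69 and Igkv12-44 led in all 3 P1 libraries (55.53% to 96.8% and 62.96% to 97.64%), and no gene passed 9.338% in a WT library.

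Genes of dividing cells rose. Of 52 tested G2 and mitosis genes, 51 were higher and 0 lower (52 and 0 when adjusted over the list alone), with a median log2 fold change of 3.37. The list passed a competitive test with a preset correlation (limma camera adjusted p = 5.43e-29), but not with an estimated one (adjusted p = 0.256 with an estimated correlation). Mki67 rose by 5.25 ± 0.59 (edgeR adjusted p = 0.000834), from 59.8 ± 15.6 to 2281 ± 1387 CPM. Espl1 rose by 4.38 ± 0.30 (adjusted p = 0.000337), Dlgap5 by 3.87 ± 0.26 (adjusted p = 0.000337) and Tpx2 by 3.63 ± 0.27 (adjusted p = 0.000359). Of 46 S phase and DNA replication genes, 34 were higher and 0 lower (39 and 0 over the list alone), with a median of 1.86 (camera adjusted p = 1.82e-15, and adjusted p = 0.256 with an estimated correlation). Mcm10 rose by 4.13 ± 0.33, Rrm2 by 3.69 ± 0.29, Ccne1 by 2.63 ± 0.25 and Mcm2 by 1.75 ± 0.29 (adjusted p = 0.000405, 0.00039, 0.000579 and 0.00313).

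Of 19 D cyclin, CDK and CDK inhibitor genes, 11 were higher and 0 lower (15 and 0 over the list alone; median 1.12, camera adjusted p = 8.94e-06, and adjusted p = 0.256 with an estimated correlation). E2f2 rose by 4.18 ± 0.74 (adjusted p = 0.0043), with 595, 2495 and 367 CPM in P1 replicates 3, 4 and 5. The CDK inhibitors Cdkn1a and Cdkn2c rose by 3.93 ± 0.48 and 3.62 ± 0.40 (edgeR adjusted p = 0.000989 and 0.000788). Ccnd3 rose by 1.02 ± 0.28 (adjusted p = 0.0265), a call lost without WT A, B or C (0.138, 0.141 and 0.086). Ccnd2 was at 0.43 (adjusted p = 0.405) and Cdk4 at 1.12 (adjusted p = 0.0626), which passed without P1 replicate 4 (0.0237). B-cell-centred scaling called both higher (3.31 and 3.79, adjusted p = 0.001 and 0.000298), values that include its shift of 2.87.

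Genes of mature B cells were lower, some of them by far more than others. Cr2 (chromosome 1, 194819119 to 194859024) fell by 9.17 ± 1.04 on the log2 scale (edgeR adjusted p = 0.000831), from 723 ± 154 to 1.05 ± 1.63 CPM. Fcer2a (chromosome 8, 3731737 to 3744175) fell by 8.13 ± 1.00 (adjusted p = 0.00107), from 593 ± 81.1 to 1.89 ± 2.68 CPM, and these 2 stayed lower under B-cell-centred scaling, at -6.52 and -5.41. Of 18 follicular B cell genes, 0 were higher and 16 lower (0 and 16 over the list alone; median -3.21), while under B-cell-centred scaling 5 were higher and 4 lower. The camera adjusted p of this list was 9.49e-09, and adjusted p = 0.256 with an estimated correlation. It still passed camera downward under B-cell-centred scaling, which changes little in a comparison with other genes. Of 25 pan-B cell genes, 0 were higher and 23 lower (0 and 24 over the list alone; median -2.55), and under B-cell-centred scaling, which evens out this list by construction, 5 were higher and 4 lower. Its camera adjusted p was 1.48e-12, and adjusted p = 0.256 with an estimated correlation.

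Among the pan-B genes, Ebf1 and Bank1 fell (-4.13 ± 0.36 and -4.37 ± 0.67; adjusted p = 0.000499 and 0.00242), and both stayed lower under B-cell-centred scaling (-1.39 and -1.65). Ms4a1 fell by 3.13 ± 0.54 (adjusted p = 0.00378), and was -0.42 under that scaling and no longer called. Pax5 and Cd22 fell (-2.21 ± 0.45 and -1.80 ± 0.43; adjusted p = 0.00749 and 0.015), and B-cell-centred scaling turned these to 0.46 and 0.97. The Cd22 call was lost without WT A or B (0.0603 and 0.0581). Tnfrsf13c was at -0.06 (adjusted p = 0.939), with 229 ± 31.8 CPM in WT and 220 ± 143 in P1, and at 2.69 under B-cell-centred scaling, below the 2.87 by which that scaling moved the median of all genes. Ighd fell by 5.55 ± 1.24 (adjusted p = 0.0115), from 974.7 ± 211 to 20.4 ± 30.3 CPM, and was -2.86 under that scaling. Its call was lost without a filter on low counts (-5.62, adjusted p = 0.119).

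Marginal zone B cell genes were 2 higher and 11 lower of 18 (3 and 12 over the list alone; median -1.45), but 12 higher and 2 lower under B-cell-centred scaling. Their camera adjusted p was 5.82e-05, and adjusted p = 0.256 with an estimated correlation, and the list still passed downward under B-cell-centred scaling. Dtx1 fell by 3.32 ± 0.34 (adjusted p = 0.00066; -0.31 under B-cell-centred scaling), and Notch2 fell by 1.55 ± 0.31 (adjusted p = 0.00704) but was higher by 1.31 under that scaling. B-1a cell genes were 16 higher and 0 lower of 23 (17 and 1 over the list alone; median 2.58, camera adjusted p = 2.19e-06, and adjusted p = 0.256 with an estimated correlation). Cd5 rose by 3.59 ± 0.34 (adjusted p = 0.000579), from 2.89 ± 0.522 to 34.9 ± 8.90 CPM, a gene that T cells also express. Zbtb32 rose by 4.25 ± 0.51, Bhlhe41 by 3.88 ± 0.66 and Itgam, a myeloid gene too, by 5.53 ± 0.81 (adjusted p = 0.000986, 0.00373 and 0.00207).

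Human mantle cell lymphoma-associated genes were 8 higher and 1 lower of 21 (13 and 2 over the list alone; median 1.05). The camera adjusted p was 0.0029, 0.321 under B-cell-centred scaling, and adjusted p = 0.256 with an estimated correlation. The list holds the drivers Sox11 and Ccnd1 and the T cell gene Cd5, and its median relative to all genes was 1.03, and 1.28 under that scaling. Hmgb3 rose by 3.31 ± 0.39 and Nsd2 by 1.84 ± 0.25 (adjusted p = 0.000909 and 0.00163). Cnn3 fell by 3.59 ± 0.59 (adjusted p = 0.00322), and was -0.59 and no longer called under B-cell-centred scaling. Cd24a rose by 1.42 ± 0.41 (adjusted p = 0.0322), a call lost without WT A, B or C (0.152, 0.0776 and 0.14). Progenitor B cell genes were 6 higher and 1 lower of 12 (7 and 2 over the list alone, with a median of 1.54). They did not pass (camera adjusted p = 0.0558, and 0.256 with an estimated correlation), but passed without P1 replicate 3 (0.0483), without a filter (0.0307) and with library totals (0.0372). Fry, which tests against no change rather than against other genes, gave an adjusted p of 0.0027. Myb rose by 3.20 ± 0.32 and Erg by 4.09 ± 0.57 (adjusted p = 0.000644 and 0.00166).

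Germinal centre genes were 2 higher and 7 lower of 16 (3 and 7 over the list alone; median -1.28), and 9 higher and 1 lower under B-cell-centred scaling. The list did not pass (camera adjusted p = 0.0655), but passed without WT A, WT C or P1 replicate 3 (0.0394, 0.021 and 0.0405). It also passed without a filter (0.0292), with library totals (0.0488) and under B-cell-centred scaling (4.38e-05). Under that scaling the direction was still down, with a median relative to all genes of -1.41. With an estimated correlation the camera adjusted p was 0.379. Fry, which tests against no change rather than against other genes, gave an adjusted p of 0.0239. Nuggc, a member, fell to 1 count in P1 (ratio 223, counting interval 40 to 8825; adjusted p = 0.00167), and stayed at -4.91 under B-cell-centred scaling. Ezh2 rose by 2.20 ± 0.24 (adjusted p = 0.000758). Bcl6 fell by 2.24 ± 0.55 (adjusted p = 0.0171), a call lost without WT A, WT B or P1 replicate 4 (0.0509, 0.0589 and 0.0569), and was at 0.59 under B-cell-centred scaling. Plasma cell genes were 4 higher and 1 lower of 20 (4 and 1 over the list alone; median 0.31, camera adjusted p = 0.564). Prdm1 rose by 1.81 ± 0.35 (adjusted p = 0.00642), and Irf4 fell by 1.93 ± 0.28 (adjusted p = 0.00209) but was at 1.04 under B-cell-centred scaling.

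B cell receptor signalling genes were 1 higher and 19 lower of 33 (1 and 22 over the list alone; median -1.17), but 24 higher and 2 lower under B-cell-centred scaling. For this list the camera adjusted p was 7.33e-08, and adjusted p = 0.256 with an estimated correlation. Relative to the other genes it stayed lower under that scaling, where camera still passed. Rasgrp3 fell by 4.82 ± 0.33 (adjusted p = 0.000337) and stayed lower under that scaling (-2.04). Syk fell by 1.31 ± 0.33 (adjusted p = 0.0179), a call lost without WT A, B or C (0.072, 0.0846 and 0.0818), and was higher by 1.57 under B-cell-centred scaling. NF-kappaB targets were 4 higher and 11 lower of 33 (4 and 11 over the list alone; median -0.43), but 27 higher and 0 lower under B-cell-centred scaling. In camera their adjusted p was 0.0267, 0.321 under that scaling, and adjusted p = 0.379 with an estimated correlation. The median relative to all genes was -0.44, and -0.45 under that scaling. Cd83 and Rel fell (-2.97 ± 0.38 and -2.15 ± 0.28; adjusted p = 0.00115 and 0.00136), and were at 0.07 and 0.80 under B-cell-centred scaling.

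Immediate-early and stress genes were 1 higher and 18 lower of 24 (1 and 19 over the list alone; median -2.45), and 8 higher and 5 lower under B-cell-centred scaling. Their camera adjusted p was 1.2e-08, and adjusted p = 0.256 with an estimated correlation, and the list still passed downward under B-cell-centred scaling. Jun fell by 3.98 ± 0.45 (adjusted p = 0.000812), from 2070 ± 591 to 131 ± 38.0 CPM, and was -1.16 and no longer called under that scaling. Egr3 fell by 5.69 ± 0.57 (adjusted p = 0.000644; -2.88 under that scaling). Hspa1b and Hspa1a, whose reads can be exchanged, fell (-6.60 ± 0.61 and -6.01 ± 0.80, adjusted p = 0.000569 and 0.0014) and stayed at -3.57 and -2.96. Cell selection, described for the WT samples alone, cannot be told apart from genotype and tumour as the source of these differences.

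MHC class II genes were 0 higher and 11 lower of 16 (0 and 11 over the list alone; median -1.92), but 6 higher and 1 lower under B-cell-centred scaling. The camera adjusted p was 5.82e-05, and adjusted p = 0.371 with an estimated correlation, and the list still passed downward under B-cell-centred scaling. H2-Ob fell by 4.56 ± 0.59 (adjusted p = 0.00128; -1.95 under that scaling), and H2-Aa fell by 2.55 ± 0.54 (adjusted p = 0.0092) but was at 0.07 under that scaling. Cd74 was at -1.73 (adjusted p = 0.127), and passed without P1 replicate 5 (-2.77, adjusted p = 0.0206). MHC class I genes were 2 higher and 1 lower of 18 (1 and 0 over the list alone; median 0.34, camera adjusted p = 0.211). H2-K1 was at 0.08 (adjusted p = 0.887; 2.94 and 0.00346 under B-cell-centred scaling), and Nlrc5 rose by 1.51 ± 0.30 (adjusted p = 0.00659), a call lost without WT A or B (0.0533 and 0.0643).

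Homing and adhesion genes were 1 higher and 11 lower of 22 (2 and 11 over the list alone; median -0.93), but 12 higher and 3 lower under B-cell-centred scaling. For this list the camera adjusted p was 0.00407, and adjusted p = 0.379 with an estimated correlation, and it still passed downward under B-cell-centred scaling. Cd69 fell by 4.08 ± 0.39 (adjusted p = 0.000579; -1.37 under that scaling). S1pr1, Cxcr5 and Klf2 fell (-3.51 ± 0.31, -3.63 ± 0.57 and -3.13 ± 0.45; adjusted p = 0.000511, 0.0027 and 0.00204), and were -0.74, -0.88 and -0.39 and no longer called under that scaling. Itgb1 rose by 2.42 ± 0.35 (adjusted p = 0.00192). Immunoglobulin constant genes were 1 higher and 7 lower of 11 (1 and 7 over the list alone; median -2.0), but 4 higher and 1 lower under B-cell-centred scaling. In camera their adjusted p was 0.00184, and adjusted p = 0.371 with an estimated correlation, and the list still passed downward under B-cell-centred scaling. Ighg3 rose by 2.21 ± 0.38 (adjusted p = 0.00364), and Iglc2 fell by 2.50 ± 0.32 (adjusted p = 0.00116) but was at 0.38 under B-cell-centred scaling. Ighm was at -1.08 (edgeR adjusted p = 0.13), was called lower by the DESeq2 Wald test (-1.11, adjusted p = 0.00723) and limma voom (-1.15, adjusted p = 0.0398), and was at 1.67 under B-cell-centred scaling.

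Interferon-stimulated genes were 17 higher and 0 lower of 38 (19 and 0 over the list alone; median 1.27). Their camera adjusted p was 0.000281, 0.321 under B-cell-centred scaling, 0.111 with fry, and adjusted p = 0.566 with an estimated correlation. The median relative to all genes was 1.26, and 1.38 under that scaling. Summed over the list, P1 replicate 5 had 1224 CPM, near the 1160 to 1175 CPM of the WT libraries, against 4725 and 4698 CPM in replicates 3 and 4. Abundant members weigh most in that sum. The median log2 CPM of the members was 4.8 in replicate 5, above the 3.78, 3.94 and 4.07 of WT A, B and C. It was 6.48 and 6.05 in replicates 3 and 4. Rsad2 rose by 8.37 ± 1.21 (adjusted p = 0.00198), with 1225, 1392 and 56.7 CPM in P1 replicates 3, 4 and 5. Iigp1 and Gbp2 rose by 5.91 ± 0.73 and 3.13 ± 0.34 (adjusted p = 0.00109 and 0.000788). Glycolysis genes were 11 higher and 1 lower of 21 (14 and 1 over the list alone; median 1.06, camera adjusted p = 0.000665, and adjusted p = 0.256 with an estimated correlation). Slc16a3 and Hk2 rose by 4.50 ± 0.37 and 2.68 ± 0.29 (adjusted p = 0.000405 and 0.000758). Pkm rose by 1.72 ± 0.39 (adjusted p = 0.0127), a call lost without WT A, B or C (0.0846, 0.0833 and 0.0625).

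Nuclear-encoded oxidative phosphorylation genes were 1 higher and 0 lower of 51 (0 and 0 over the list alone; median 0.28) and did not pass (camera adjusted p = 0.194), but did without P1 replicate 4 (0.00783). The 1 was Ndufb9, at 1.30 ± 0.27 (adjusted p = 0.00908), a call lost without WT A or B (0.0649 and 0.0581). MYC targets were 2 higher and 2 lower of 39 (1 and 1 over the list alone; median 0.37; camera adjusted p = 0.153, and 0.0087 without P1 replicate 3). Odc1 rose by 1.75 ± 0.29 (adjusted p = 0.00324), and Ncl was at 0.72 (adjusted p = 0.176, 0.0364 without P1 replicate 3, and 0.000932 under B-cell-centred scaling, at 3.58). BCL2 family genes were 2 higher and 3 lower of 15 (3 and 3 over the list alone; median 0.12, camera adjusted p = 0.928). Bcl2l1 rose by 6.59 ± 1.06 (adjusted p = 0.00295), with 448, 2127 and 124 CPM in P1 replicates 3, 4 and 5 against 9.33 ± 2.01 in WT. Bcl2 fell by 1.16 ± 0.25 (adjusted p = 0.0096) but was higher by 1.66 under B-cell-centred scaling, and Mcl1 was at 0.30 (adjusted p = 0.591; 3.27 and 0.0026 under that scaling). The p53 targets were 3 higher and 2 lower of 21 (3 and 2 over the list alone), with a median of -0.17 beside an upward camera statistic (adjusted p = 0.867).

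Markers of erythroid cells, neutrophils and T cells were higher in the P1 spleens than in the selected WT B cells. B cell selection removes such cells from the WT samples, and the P1 spleens were not described as selected. The values therefore do not show that these cells were more numerous than in a WT spleen. The same limit holds for the other lists of non-B cells and for the checkpoint genes. Of 25 erythroid genes, 25 were higher and 0 lower (25 and 0 over the list alone; median 7.83, camera adjusted p = 1.47e-15, and adjusted p = 0.256 with an estimated correlation). Slc4a1 rose by 10.40 ± 1.01, Hbb-bs by 10.15 ± 1.71 and Epor by 5.48 ± 0.52 (adjusted p = 0.000579, 0.00347 and 0.000579). Hba-a1 and Hba-a2, whose reads can be exchanged, rose by 10.95 ± 1.72 and 11.73 ± 1.86 (adjusted p = 0.00267 and 0.00274). Haemoglobin genes took 2.9%, 11.65% and 0.48% of counts in P1 replicates 3, 4 and 5, and at most 0.01% in a WT library. Of 22 neutrophil genes, 22 were higher and 0 lower (22 and 0 over the list alone; median 8.57, camera adjusted p = 5.55e-17, and adjusted p = 0.256 with an estimated correlation). Ngp rose by 10.27 ± 0.99 and Chil3 by 10.24 ± 0.68 (adjusted p = 0.000579 and 0.000337).

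Of 24 T cell genes, 24 were higher and 0 lower (24 and 0 over the list alone; median 3.96, camera adjusted p = 2.97e-13, and adjusted p = 0.256 with an estimated correlation). Cd8a rose by 6.23 ± 0.74 and Cd3e by 4.54 ± 0.73 (adjusted p = 0.000919 and 0.00286). Immune checkpoint genes were 13 higher and 5 lower of 24 (13 and 5 over the list alone; median 2.01). The camera adjusted p was 0.00333, 0.588 under B-cell-centred scaling, and adjusted p = 0.379 with an estimated correlation. The median relative to all genes was 1.99, 1.92 under that scaling, and 0.41 with at least 10 CPM in 3 libraries, where the call was lost (0.709). Pdcd1, Lag3 and Ctla4 rose by 6.20 ± 0.43, 3.99 ± 0.53 and 3.44 ± 0.56 (adjusted p = 0.000337, 0.0014 and 0.00311), while Btla fell by 2.89 ± 0.30 (adjusted p = 0.000719; -0.09 under B-cell-centred scaling). Regulatory T cell markers were 3 higher and 1 lower of 7 (3 and 1 over the list alone; median 1.37) and did not pass (camera adjusted p = 0.148, and 0.00852 without P1 replicate 4). Foxp3 was at 1.03 (adjusted p = 0.137), and was called higher under B-cell-centred scaling (3.81, adjusted p = 0.000634).

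NK cell markers were 6 higher and 0 lower of 13 (7 and 0 over the list alone; median 1.62, camera adjusted p = 0.0427, and adjusted p = 0.639 with an estimated correlation). That call was lost without WT A, WT B, P1 replicate 3 or P1 replicate 5 (0.0721, 0.0643, 0.392 and 0.107), without a filter (0.143) and under B-cell-centred scaling (0.321), where the camera statistic changed direction. Fry, which tests the list against no change, did not pass either (adjusted p = 0.116). Eomes and Nkg7 rose by 3.70 ± 0.41 and 4.58 ± 0.78 (adjusted p = 0.000813 and 0.00374). Monocyte and macrophage markers were 8 higher and 0 lower of 26 (8 and 0 over the list alone; median 1.16). For this list the camera adjusted p was 0.00239, 0.395 under B-cell-centred scaling, and adjusted p = 0.519 with an estimated correlation. The median relative to all genes was 1.14, and 1.09 under that scaling. Msr1 rose by 7.5 ± 0.74 (adjusted p = 0.000622), and Lyz2 rose by 5.24 ± 1.23 (adjusted p = 0.0143), a call lost without WT A or B (0.0619 and 0.0707).

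Dendritic cell markers were 3 higher and 1 lower of 12 (3 and 1 over the list alone; median 0.86, camera adjusted p = 0.455). Batf3 rose by 3.09 ± 0.74 (adjusted p = 0.016), a call lost without WT A or B (0.0719 and 0.0777). Wdfy4 fell by 1.5 ± 0.44 (adjusted p = 0.0344) but was at 1.16 under B-cell-centred scaling, and its call was lost without WT A, WT B, WT C or P1 replicate 3 (0.102, 0.104, 0.0995 and 0.0578). Megakaryocyte markers were 1 higher and 0 lower of 16 (1 and 0 over the list alone), with a median of -0.06 beside an upward camera statistic (adjusted p = 0.628). The 1 was Selp, at 2.71 ± 0.59 (adjusted p = 0.0103), a call lost without WT A, B or C (0.0523, 0.0581 and 0.0502). Stromal and endothelial markers were 9 higher and 1 lower of 16 (9 and 1 over the list alone; median 3.67). In camera their adjusted p was 0.000665, 0.698 under B-cell-centred scaling, and adjusted p = 0.379 with an estimated correlation. The stromal median relative to all genes was 3.65, 4.14 under that scaling, and 1.05 with at least 10 CPM in 3 libraries, where the call was lost (0.434). Fn1 rose by 6.46 ± 0.84 (adjusted p = 0.00133), Col3a1 rose from 1 WT count (ratio 136, counting interval 24 to 5461; adjusted p = 0.00108), and Pecam1 fell by 1.65 ± 0.26 (adjusted p = 0.00268) but was at 1.33 under B-cell-centred scaling.

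**Figure D3:**
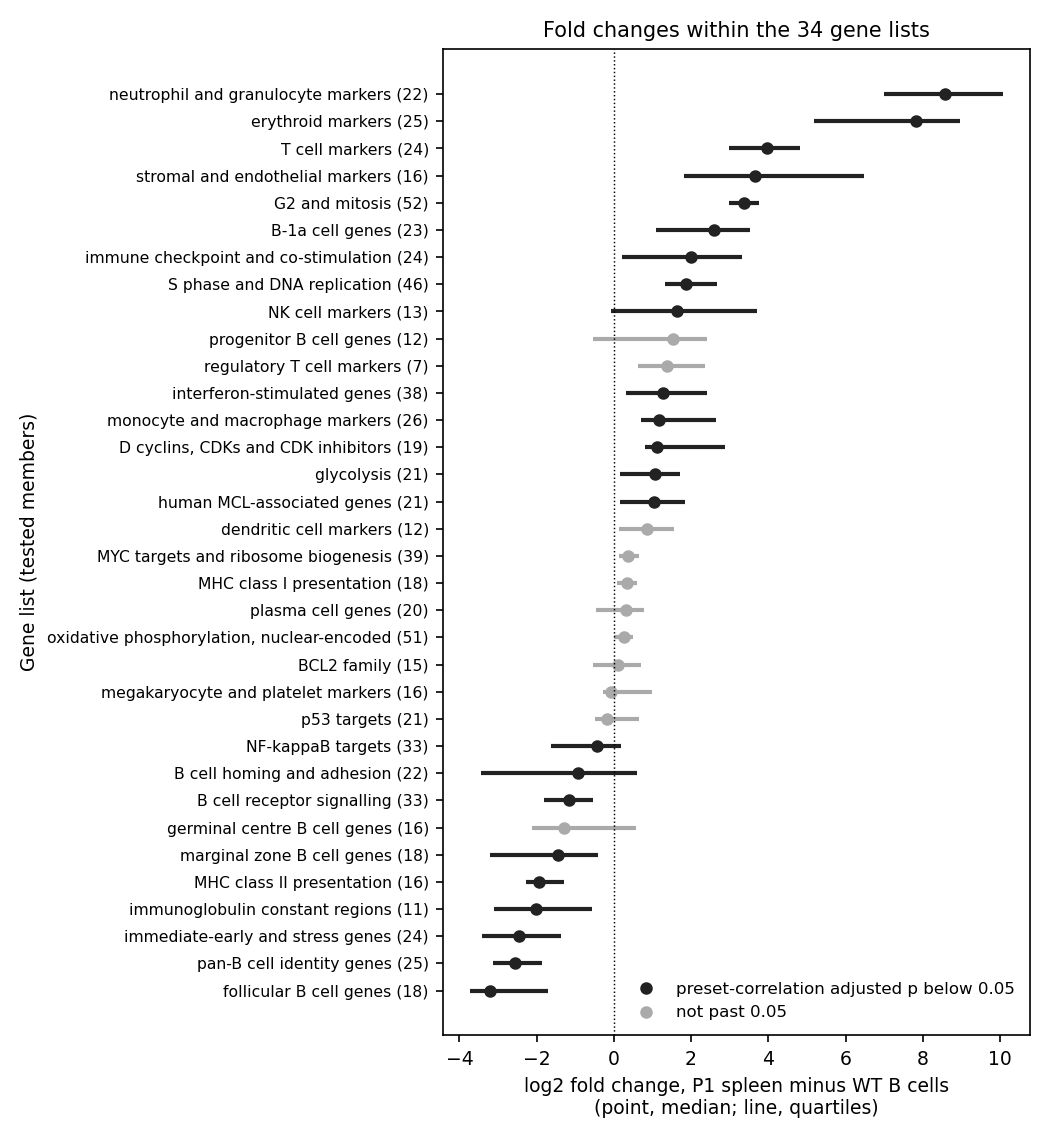
Median and quartiles of the log2 fold changes in each of the 34 tested lists. Medians ran from 8.57 (neutrophil) to -3.21 (follicular B cell), where B-cell-centred scaling called 5 follicular members higher and 4 lower. The follicular list still passed camera downward under that scaling, which changes little in a comparison with other genes.

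Outside the gene lists, the highest log2 fold changes included Apol11b, Itgb2l, Saa3, Apol11a and Strc. Apol11b rose by 13.39 ± 1.45 (edgeR adjusted p = 0.00078), and Apol11a from 1 WT count (ratio 8734, counting interval 1567 to 345057; adjusted p = 0.000599), 2 close paralogs whose reads can be exchanged. Saa3 rose from 1 WT count (ratio 8458, 1517 to 334133; adjusted p = 0.000222) and Slfn4 from 2 (ratio 2970, 821 to 24531; adjusted p = 0.000511). Itgb2l, Strc and Stard13 had 0 WT counts and were at least 1122-fold, 773-fold and 476-fold higher, taking 3 counts over the WT group (adjusted p = 0.00086, 0.000882 and 0.000405). Which cells carried the rises of these genes was not tested, and the B cell selection of the WT samples alone could give them. Among the lower genes, Ryr2 and Crisp3 had 2 and 3 counts left in P1 (ratios 137 and 89, with intervals 38 to 1132 and 30 to 435; adjusted p = 0.000734 and 0.00144). Hs3st1, Sema5a and Pxdc1 fell (-6.70 ± 0.38, -6.01 ± 0.58 and -5.98 ± 0.71; adjusted p = 0.000222, 0.000579 and 0.00096). All 5 of these lower genes stayed called lower under B-cell-centred scaling.

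Mitochondrial genes took 3.4%, 17.36% and 0.09% of counts in P1 replicates 3, 4 and 5 and 0.57%, 1.13% and 0.59% in WT A, B and C. The P1 libraries were also less alike (Spearman correlation 0.904 to 0.915) than the WT libraries (0.982 to 0.986), with 0.741 to 0.829 between the groups.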

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

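Sox11 and Ccnd1 stayed past the threshold and higher under every setting but the fold threshold, which was run for gene counts alone, with log2 fold changes of 12.97 to 16.98 and 4.79 to 8.13. The higher and lower genes numbered 2638 and 1704 with DESeq2 size factors, 2607 and 1704 with TMM without immunoglobulin, haemoglobin, mitochondrial and ribosomal RNA genes, 3234 and 1912 without a filter, 3694 and 2184 with the DESeq2 Wald test, and 2436 and 1954 with limma voom. Library totals without TMM factors, chosen after seeing the data, gave 1928 and 1459. They moved to 13872 and 112 under B-cell-centred scaling, whose construction raises the median of all genes, and of the 4320 genes called, 3467 were called there, 2730 in the same direction. They moved to 1445 and 1060 with at least 10 CPM in 3 libraries, where only 9108 genes were tested, and to 1664 and 662 with a fold threshold of 2, which asks for a larger change. Without single libraries they ran from 1644 to 3206 higher and 815 to 2313 lower, and were smallest without a WT library. The cause was not tested.

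Gene lists past the threshold numbered 23 with DESeq2 size factors and TMM without the abundant RNA classes, 23 with fry (20 of the 23), 19 under B-cell-centred scaling (16 of the 23), 25 without a filter, 20 of 31 tested with at least 10 CPM, 25 with library totals, and 22 to 25 without single libraries. With an estimated correlation 0 passed (adjusted p 0.26 to 0.94), with estimated correlations of -0.037 to 0.797 against the preset 0.01. The size of the correlation cannot be the whole cause. Camera adjusted p went from 8.94e-06 to 0.256 for the D cyclin list (estimate 0.032). It went from 0.0558 to 0.256 for the progenitor list (0.008, below the preset). With an estimated correlation camera uses the residual degrees of freedom, which are few with 3 libraries per group. A list that did not pass there is therefore not shown to be unchanged. The cause was not tested further. Fry asks another question, whether a list differs from no change. Interferon-stimulated, NK cell and macrophage lists did not pass with fry (adjusted p = 0.111, 0.116 and 0.116). The germinal centre, plasma cell and progenitor lists passed fry (0.0239, 0.0175 and 0.0027), which does not show a difference from other genes. The plasma cell list had a camera adjusted p of 0.564. MYC and oxidative phosphorylation lists passed under B-cell-centred scaling (0.00571 and 0.000376), and the regulatory T cell list without a filter (0.0355). The Ighv and Igkv share differences ran from 66.78 to 87.42 and from 73 to 90.34 points without single libraries. They were 3.509 and 4.075 points of all immunoglobulin counts.

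Of 112 named genes, 102 were past the threshold, and 89 of these stayed past it in the same direction under every setting with a value except B-cell-centred scaling. With at least 10 CPM, 12 genes had no value. Without a filter the calls of Ccnd3 (adjusted p = 0.06), Lyz2 (0.141) and Ighd (0.119) were lost. With library totals those of Ccnd3 (0.233), Cd24a (0.108), Ndufb9 (0.116), Nlrc5 (0.0568) and Wdfy4 (0.0507) were lost. The DESeq2 Wald test gained Cdk4 (0.0481), Cd74 (0.0248) and Ighm (0.00723). B-cell-centred scaling called 6 further genes higher and turned the sign of 17, all below its shift of 2.87 by construction: Pax5 0.46, Cd22 0.97, Tnfrsf13c 2.69, Notch2 1.31, Syk 1.57, H2-Aa 0.07, Cd74 0.74, Bcl6 0.59, Irf4 1.04, Ighm 1.67, Iglc2 0.38, Cd83 0.07, Rel 0.80, Bcl2 1.66, Wdfy4 1.16, Pecam1 1.33 and Xist 2.08. Over the other settings 8 of 1444 values reversed, all in genes not past the threshold. These were Tnfrsf13c without WT B (0.02), P1 replicate 3 (0.28) or P1 replicate 4 (0.08), Mcl1 with library totals (-0.05), and H2-K1 without a filter (-0.04), without WT B (-0.05), without P1 replicate 5 (-0.02) and with library totals (-0.17). Without single libraries Tnfrsf13c ran from -0.73 to 0.28 and H2-K1 from -0.05 to 0.17. The cause was not tested.

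The direction of the camera statistic reversed for NK cell, dendritic cell and megakaryocyte lists under B-cell-centred scaling (medians relative to all genes 1.45, 0.88 and -0.04) and for the BCL2 family without a filter (-0.02). Leaving out single libraries reversed it for the BCL2 family (WT A 0.02, WT B 0.11 and P1 replicate 5 -0.27; range -0.27 to 0.16) and p53 targets (WT A -0.27 and P1 replicate 4 -0.08; range -0.27 to -0.08). It also reversed for megakaryocyte genes (WT A -0.23; range -0.50 to 1.02), dendritic cell genes (P1 replicate 3 -0.69; range -0.69 to 1.18) and MYC targets (P1 replicate 5 0.10; range 0.10 to 0.60). Of these 6 lists the NK cell list alone had passed. The cause was not tested.

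No paired analysis was made, since WT mice and P1 recipients are separate groups of mice and the labels give no pairing. Depth limits low genes: a group total of 1 to 3 counts leaves wide intervals, as for Sox11 in WT (3509 to 772483).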

Other observations

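The tests of the pan-B, mitosis and Bcl2l1 patterns, the chromosome medians and the splits were chosen after the results were seen. P1 replicate 3 had the lowest CPM of both driver genes and the lowest share of its V-gene counts in Ighv1-69 and Igkv12-44, but not the lowest CPM of these V genes. Sox11 counts per Ighv1-69 count were 0.49, 7.74 and 2.36 in P1 replicates 3, 4 and 5, and Ccnd1 counts per Ighv1-69 count 0.63, 4.3 and 2.47. The normalised level of Ighv1-69 was 168.3, 121.5 and 274 CPM and that of Igkv12-44 198.9, 181.6 and 219.8 CPM. Xist had 594, 524 and 60.2 CPM in these libraries against 800 ± 188 in WT (log2 fold change -1.03, edgeR adjusted p = 0.313).

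In 7 chromosomes a P1 library's median log2 ratio to WT lay more than 0.2 from that of all genes. On chromosome 15 this difference was 0.13, 0.18 and 0.34 in P1 replicates 3, 4 and 5, on chromosome 6 it was 0.10, 0.03 and 0.30, and on chromosome 18 it was 0.03, 0 and 0.22. On chromosome 12 it was -0.17, -0.28 and -0.37, on chromosome 14 -0.06, -0.27 and -0.41, on chromosome 1 0.02, -0.01 and -0.23, and on X -0.02, -0.24 and -0.30. In the WT libraries these chromosomes lay between -0.07 and 0.14. Immunoglobulin genes were kept in these medians. Chromosomes 12 and 6 hold the Ighv and Igkv genes, so the loss of most V genes in P1 replicates 4 and 5 can lower their medians. That could bear on the lower values of chromosome 12, but would work against the higher ones of chromosome 6. These medians do not measure copy number. An unnamed gene model on chromosome 17 (40158994 to 40159718) took 6.36%, 6% and 9.46% of counts in WT A, B and C and 5.93%, 13.54% and 13.13% in P1 replicates 3, 4 and 5.

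Pan-B cell genes fell unequally. Dilution of B cells by cells that express none of these genes would lower all of them by the same amount. The smallest SD of their log2 ratios in a P1 library (0.93) was 3.87 times the largest in a WT library (0.24). This argues against dilution by such cells as the only cause. Dilution by cells that express some of these genes was not tested, and the WT libraries are replicates of 1 selected population. The overall fall (median -2.55) may still come from fewer B cells among the cells that gave the RNA. That cannot be told apart from lower expression, since the P1 spleens were not described as B cell selected.

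The rise of G2 and mitosis genes was compared with lists of cells that might carry it, between the 2 P1 libraries furthest apart in each list. Mitosis genes differed by a median of 0.12 where erythroid genes differed by 2.69, by 0.18 where neutrophil genes differed by 2.46, and by -0.12 where pan-B genes differed by 1.24. The first 2 values argue against erythroid or neutrophil precursors as the only source of the list as a whole. This holds only if these markers follow the number of dividing precursors, which was not tested. Mki67 alone differed by 1.75 between replicates 4 and 5, in the direction of the erythroid genes. B lineage cells as the only source stay open, since the lymphoma markers disagreed in that last pair, replicates 5 and 4. Sox11 moved against the pan-B genes (-0.54). Ccnd1 (677 and 522 CPM), Ighv1-69 (274 and 121.5 CPM) and Igkv12-44 (219.8 and 181.6 CPM) moved with them. Whether pan-B genes tracked the lymphoma cells there is therefore not known. A mixture of dividing lymphoma and precursor cells could give an even level and stays open too.

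The source of Bcl2l1 stays open. Bcl2l1 differed by 4.1 between P1 replicates 4 and 5, inside the wide erythroid range (0.09 to 6.26), and lay inside the erythroid quartiles in 1 of the 3 pairs of P1 libraries, so erythroid cells as the source were not decided. For stromal and endothelial cells as the source, Bcl2l1 lay inside the stromal range in 3 of the 3 pairs and inside the quartiles in 2. All stromal markers together had 812.2 CPM in replicate 4 and Hbb-bs 117252 CPM, against 2127 CPM of Bcl2l1, but no measured profile sets what a share of either cell type would bring. Bcl2l1 lay inside the pan-B range in 0 of the 3 pairs, but B lineage cells as the only source stay open, since the lymphoma markers disagreed. Sox11 and Ccnd1 did not follow the pan-B genes in every pair. Ighv1-69 (168.3, 121.5 and 274 CPM in P1 replicates 3, 4 and 5) and Igkv12-44 (198.9, 181.6 and 219.8 CPM) did, and Bcl2l1 did not move with them.

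The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4320 genes and the highest of the other splits 0, so 1 of 10 splits gave as many. The real split put 23 lists past the threshold and the highest other split 22, so 1 of 10 gave as many.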
